A study of Mus musculus with 6 samples.

How the data were processed

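RNA was measured in plasma cells, the antibody-secreting cells of the B lineage, sorted from the bone marrow of C57BL/6J mice as cells with high CD138 and high CD267. The genes of these surface proteins are Sdc1 and Tnfrsf13b. Per the labels, mice received a regular or a ketogenic diet for 3 weeks, 10000 cells were sorted per library, and each diet has 3 libraries. Total RNA was purified with a column kit, reverse transcribed and amplified by PCR with a whole-transcriptome kit made for single cells, and 10 ng of amplified cDNA entered a transposase-based Illumina library kit, per the labels' protocols. No molecular identifiers are described, so amplified copies of 1 molecule are counted separately.

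The deposited table holds raw counts of reads per gene, whole numbers that the authors did not normalize, for 55291 gene symbols and all 6 libraries, with a gene length column. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, STAR without a version, featureCounts 2.0.1 and the mouse build GRCm38. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Reads that match several immunoglobulin genes, ribosomal protein pseudogenes or overlapping genes were therefore divided in a way that is not known. Coordinates and exon overlaps are those of the deposited table. Gene types were taken from GENCODE release M21 on GRCm38 by symbol, and 53292 symbols matched. No row lacked a gene name.

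Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10, a minimum total of 15), which left 9532 genes. Library sizes were scaled by TMM, dispersions were estimated with estimateDisp, and the quasi-likelihood F test (robust glmQLFit, two-sided) compared ketogenic with regular diet, with diet as the only term. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Levels are TMM-normalised CPM (a count relative to the scaled library total), computed here from the deposited counts, as mean ± SD of 3 libraries. Log2 fold changes are ketogenic over regular with a standard error (SE) derived from the test, the absolute log2 fold change over the square root of F.

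Before the data were examined, 38 gene lists were fixed, covering plasma cell function, metabolism, cell processes and markers of other bone marrow cells, together with the tests, the rule for named genes and most alternatives. Of 1007 list symbols, 2 were matched under an older name and 2 were not matched. The 33 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1, preset inter-gene correlation 0.01, Benjamini-Hochberg over lists). Each list's genes were also adjusted over the list alone. The named genes are the 2 sort gate genes, the 3 genes with the highest CPM, up to 4 members of each list with the smallest p, and the 10 largest changes in each direction past the threshold. Those changes had to have a mean log2 CPM of at least 2 and no overlap between diets, and variable, diversity and joining segments, predicted genes and pseudogenes were left out. Since no gene passed, the 5 with the smallest p in each direction are given instead, as the rule provides. The rule named 154 genes. To keep the text short, lists that did not pass are represented by the member with the smallest p or by none, a shortening made after the values were seen. All 154 genes were carried through every alternative in which they were tested.

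The share of each heavy-chain class in the counts of all heavy-chain constant genes was compared by two-sided exact permutation tests, added after the gene results had been seen. With 3 against 3 libraries the smallest p these tests can give is 0.1. Ratios for genes near 0 counts have 95% exact intervals conditional on the summed counts, and a floor of 3 counts over the group is used where a diet has 0. These intervals and floors treat each read as an independent count and pool the libraries of a diet. Since amplified copies of a molecule are counted separately, they do not cover the counting error of molecules. They also leave out the spread between libraries.

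Alternatives were other scaling factors, immunoglobulin genes and Jchain removed before scaling, no filter or a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust estimation switched off, the replicate number as a term, each library left out in turn, and other forms of the list test. The edgeR and camera steps were tested on simulated counts with the means, library sizes and spread of this comparison, where 8590 genes were run. Of 100 genes changed 4-fold 7% were recovered, and of 100 genes changed 16-fold 35% were, or 100% of the 16 among them with a log2 CPM of at least 5. A list of 77 genes shifted 1.5-fold gave a camera p of 0.00016, and an unshifted one 0.709. Genes were simulated independently of each other, whereas the real ribosomal list had an estimated correlation of 0.786. The simulation therefore does not show how often camera calls correlated lists without a shift. Of 8352 unchanged simulated genes, edgeR called 3.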

Results

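The series asked how a ketogenic diet alters gene expression in bone marrow plasma cells. Plasma cells sorted by high CD138 and high CD267 were profiled by RNA sequencing after 3 weeks of a regular or a ketogenic diet, with 3 libraries per diet. The regular diet libraries held 20870157, 14218110 and 14611700 counts and the ketogenic diet libraries 17523481, 22471665 and 13797941 counts. Immunoglobulin genes, with Jchain counted among them, took 81.4%, 80.8% and 80.6% of the counts on the regular diet and 76.1%, 77.1% and 79.9% on the ketogenic diet. That left 2728064 to 5141076 counts per library for all other genes. Regular replicate 1 and ketogenic replicate 2 stood apart: 13.1% and 15.1% of the tested genes had no count in them, against 1.91% to 6.997% in the other 4 libraries. Their mean Spearman correlations of log2 CPM with the other libraries, across genes, were 0.735 and 0.691. Ketogenic replicate 1 followed at 0.746, and the other 3 libraries had 0.788 to 0.796. The highest correlation of all, 0.864, joined regular replicate 2 and ketogenic replicate 3, of different diets. In a principal component analysis of log2 CPM, the first 3 components took 36.4%, 28.7% and 18.5% of the variance. They set apart ketogenic replicate 2, regular replicate 1 and ketogenic replicate 1 in turn, and the diets overlapped on each. Nothing states that the libraries came from separate mice, so p-values measure the spread between these samples, which may be technical.

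On average over all libraries, the 3 most abundant transcripts were those of secreted antibody. Igkc, the kappa light-chain constant gene, took 31.5 ± 2.90% of all counts on the regular diet and 28.3 ± 2.81% on the ketogenic diet (SD, n = 3 each). Jchain, which joins IgM and IgA into polymers, took 6.34 ± 0.656% and 7.35 ± 0.977%. Ighm, the IgM constant gene, took 18.6 ± 2.99% and 7.62 ± 4.05%. Of the genes of the sort gate, Sdc1 (CD138) stood at 420.3 ± 81.3 and 251 ± 123 CPM, a log2 fold change of -0.74 ± 0.43 (SE) that lay within the spread between libraries. Tnfrsf13b (CD267) stood at 207 ± 41.8 and 136 ± 27.6 CPM, a log2 fold change of -0.61 ± 0.30, with all 3 ketogenic libraries below all 3 regular ones. Neither passed the edgeR test, and none of the 67 tested sort gate genes and markers of other cell types did.

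The shares of the antibody classes separated all ketogenic from all regular libraries, although no exact test of 3 against 3 can pass 0.05. On the regular diet Ighm made up 85.6 ± 2.86% of the counts of heavy-chain constant genes, Igha, the IgA gene, 10.9 ± 3.01%, and the 4 IgG genes together 3.52 ± 0.374% (SD, n = 3). On the ketogenic diet the shares were 40.2 ± 15.7% for Ighm, 37.9 ± 16.5% for Igha and 21.9 ± 4.50% for IgG. For each of the 3 classes, every ketogenic library lay outside the range of the regular libraries. Ighg1 stood at 0.271 ± 0.112% and 7.77 ± 2.44%, Ighg2b at 1.21 ± 0.499% and 7.66 ± 1.02%, Ighg2c at 0.812 ± 0.668% and 4.35 ± 2.91%, and Ighg3 at 1.23 ± 0.793% and 2.09 ± 1.45%. Lambda chains made up 5.78 ± 2.77% and 9.84 ± 3.91% of light-chain constant counts. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, for Ighm, Igha, IgG, Ighg1, Ighg2b and Ighg2c, and 0.167 after Benjamini-Hochberg adjustment over 10 shares. Exact permutation p was 0.6 for Ighg3 and 0.3 for lambda. The heavy-chain shares rest on 3024587 to 3870362 heavy-chain constant counts per library, and the lambda share on 4035874 to 7548645 light-chain constant counts.

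**Figure D1:**
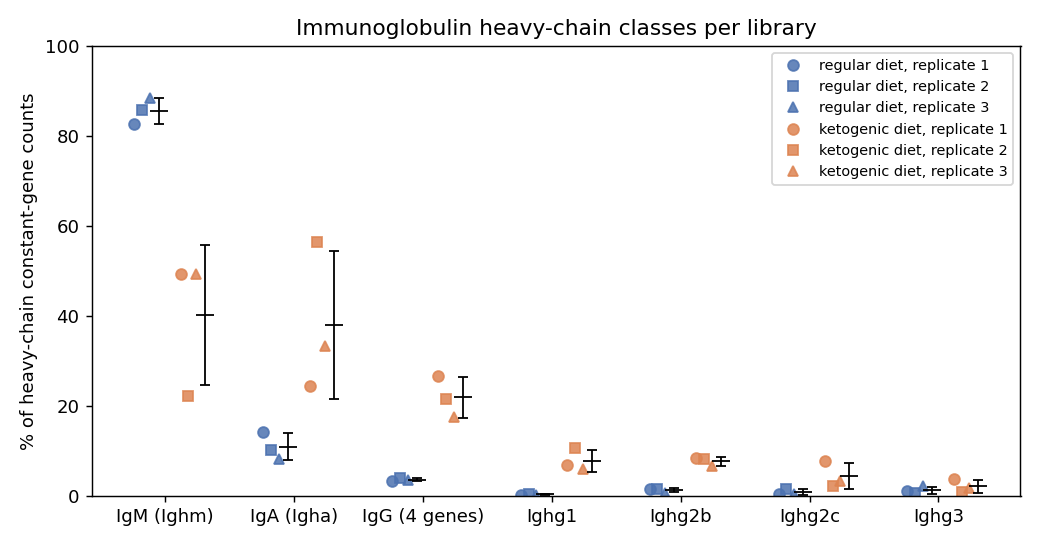
Share of each heavy-chain class in the counts of all heavy-chain constant genes (y axis, percent), with 1 point per library, blue for the regular and orange for the ketogenic diet; bars are mean ± SD of 3 libraries. The 3 ketogenic libraries had 22.1% to 49.2% Ighm against 82.6% to 88.3% on the regular diet.

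As single genes, Ighg1 and Ighg2b stood out within the list of immunoglobulin constant regions. Ighg1 (chromosome 12, 113325240 to 113330523, GRCm38) had 621 ± 316 CPM on the regular and 13090.2 ± 1275 CPM on the ketogenic diet, 21.1-fold more, a log2 fold change of 4.40 ± 0.63 (SE). Ighg2b (chromosome 12, 113302965 to 113307933) had 2641 ± 982 and 13283 ± 1952 CPM, a log2 fold change of 2.33 ± 0.55. Igha had a log2 fold change of 1.43 ± 0.61, Ighg2c of 2.05 ± 0.83 and Ighm of -1.36 ± 0.76. The Ighg2c ratio of means of 4.13 was 8.56 without regular replicate 2 and 2.63 without ketogenic replicate 1. Adjusted over the list alone, Ighg1 (adjusted p = 0.00125) and Ighg2b (adjusted p = 0.0154) rose by edgeR's test and the other 10 tested members did not pass. In the list of niche receptors and adhesion genes Ccr10, the receptor for CCL27 and CCL28 carried by IgA plasma cells, rose from 13.9 ± 2.62 to 46.3 ± 18.8 CPM, a log2 fold change of 1.74 ± 0.37 (adjusted p = 0.0476 over the list alone). By edgeR these 3 genes were the only ones among all lists to pass in this way, and 0 passed over all genes tested. DESeq2 called Ighg1 (adjusted p = 2.45e-18), Ighg2b (8.15e-06), Igha (0.015) and Ccr10 (0.0215) over the genes that it adjusted, and limma-voom called Ighg1 among them. Without ketogenic replicate 1 the count over the lists alone was 1, and without ketogenic replicate 3 it was 73, of which 69 were higher.

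Across all 9532 tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p = 0.993). At an unadjusted p under 0.05 there were 350 genes, 195 higher and 155 lower on the ketogenic diet. The nominal share of 0.05 would be 477 genes, but the test ran below it, with 3.86% of unchanged simulated genes under 0.05. DESeq2 called 54 genes (31 higher and 23 lower), of which 14 were immunoglobulin segments, and had 790 at an unadjusted p under 0.05. It gave no adjusted p to 6262 genes that had a p, and called 24 to 280 genes in other splits of the libraries. Limma-voom called 3, with 750 unadjusted: Ighg1 (adjusted p = 0.00374) and the kappa segment Igkv8-28 higher, and the kappa segment Igkv4-68 lower, the last 2 named after their values were seen. The libraries did not overlap between diets for 517 higher and 602 lower genes, 11.7% of those tested, where chance gives 10%. The biological coefficient of variation between libraries of a diet was 0.936.

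Besides Ighg1, Ighg2b and Ccr10, the genes with the smallest p on the higher side were Slpi, a secreted inhibitor of leukocyte proteases, with 449 ± 59.2 and 2594 ± 1851 CPM (log2 fold change 2.53 ± 0.58, with a ratio of means of 5.78 that was 3.41 without ketogenic replicate 2), and Ccdc107 with 12.8 ± 1.49 and 33.6 ± 8.47 CPM (1.39 ± 0.34). On the lower side, Tnfrsf1b, the type 2 receptor for tumour necrosis factor, had 417 counts over the regular and 2 over the ketogenic libraries, a depth-scaled ratio of 236 with a 95% counting interval of 64.9 to 1954, and both ketogenic counts came from replicate 2. Cenpo, a centromere protein gene, had 492 and 3 counts, a ratio of 185 with an interval of 63.1 to 903. These intervals treat reads as independent and leave out the spread between libraries, so they do not bound the change between diets. Most of the Cenpo counts came from regular replicate 1, without which there were 78 and 3 counts and a ratio of 51.3 (16.9 to 254). All 3 ketogenic Cenpo counts came from replicate 3, and the ratio was 109 (37.1 to 531) without ketogenic replicate 2. Asf1b, a histone chaperone used in DNA replication, had 18.2 ± 8.03 and 3.35 ± 0.919 CPM (log2 fold change -2.45 ± 0.56). The receptor gene Gpr18 had 35.7 ± 9.06 and 13.8 ± 1.24 CPM (-1.37 ± 0.33), and Nrros, which anchors latent TGF-beta, had 46.4 ± 9.08 and 16.5 ± 8.14 CPM (-1.50 ± 0.40). None of these passed edgeR's adjustment over all genes. DESeq2 called Slpi (adjusted p = 0.00304), Ccdc107 (0.0499), Tnfrsf1b (1.69e-06), Cenpo (0.00413), Asf1b (0.0075) and Gpr18 (0.0499), and not Nrros. Exons of Cenpo share 22.5% of their length with Adcy3 and Ptrhd1, and those of Ccdc107 share 8.02% with Rmrp. Of the list members given, Slc16a6 shares 23.5% with Amz2, Arsg and a predicted gene, Rpl32 20.04% with Cand2 and Snora7a, and Rps13 3.23% with Snord14a, so their counts can include reads of those neighbours.

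**Figure D2:**
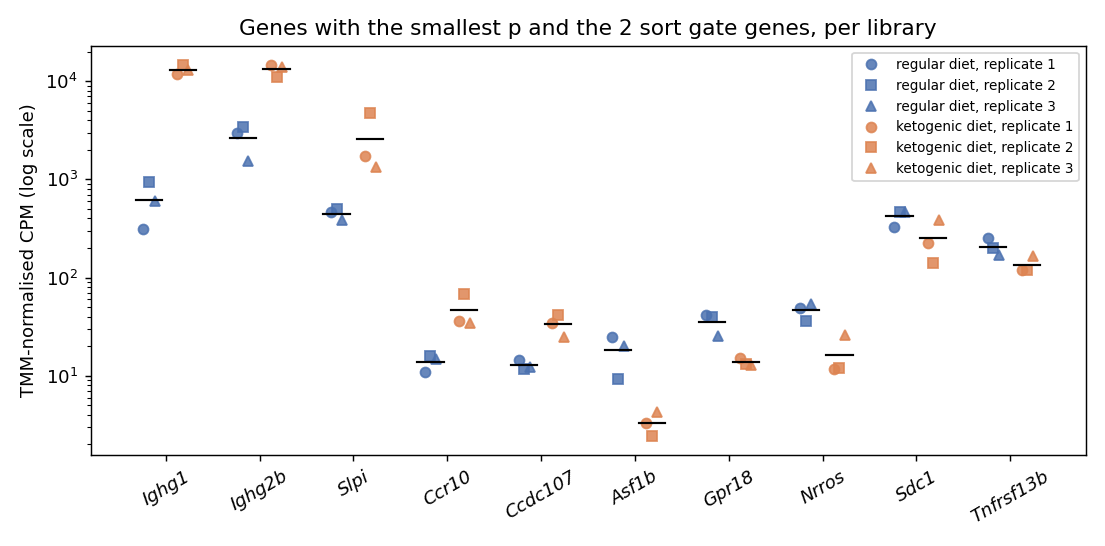
TMM-normalised CPM on a log axis for 8 of the genes named for the smallest p in each direction and the sort gate genes Sdc1 and Tnfrsf13b. Each library has 1 point, and a bar marks each mean. Tnfrsf1b and Cenpo, which had ketogenic libraries without counts, are not shown. Ighg1 lay between 315 and 947 CPM on the regular and between 11939 and 14462 CPM on the ketogenic diet.

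Among the gene lists, ribosomal protein genes were shifted upward on the ketogenic diet, with a median log2 fold change of 0.81 and a positive value for all 77 tested members. Their summed level was 6172, 6210.0 and 5542 CPM in the regular libraries and 9814, 13905 and 6395 CPM in the ketogenic libraries. Examples were Rps13 (27.9 ± 1.91 and 72.7 ± 35.0 CPM), Rpl23 (49.6 ± 5.15 and 116 ± 52.8 CPM), Rpl29 (28.2 ± 4.34 and 54.2 ± 11.7 CPM) and Rpl32 (101 ± 16.2 and 229 ± 103 CPM). Nuclear genes of the respiratory chain were shifted upward with a median of 0.57 over 73 members, of which 64 were positive. Ndufa3 of complex I had 42.9 ± 2.11 and 86.5 ± 43.8 CPM, and Cox6a1 of complex IV 108 ± 4.24 and 191 ± 82.3 CPM. The 8 tested mitochondrially encoded genes had a median of 0.66, with mt-Nd2 at 85.9 ± 19.1 and 175 ± 68.0 CPM. All mitochondrial genes together took 0.224%, 0.54% and 0.34% of the counts in the regular and 1.17%, 0.854% and 0.403% in the ketogenic libraries. Camera gave adjusted p = 3.74e-26 for the ribosomal list, 5.84e-09 for the nuclear respiratory list and 0.00922 for the mitochondrially encoded list. These were adjusted p = 0.708, 0.789 and 0.708 with an estimated correlation. By edgeR with all 6 libraries, no single member of these lists passed, adjusted over the list alone or over all genes. Without ketogenic replicate 2 the nuclear respiratory list no longer passed (adjusted p = 0.189) and the mitochondrially encoded list had an adjusted p of 0.0903. Without both ketogenic replicate 2 and regular replicate 1 the nuclear respiratory list passed (0.000809). The mitochondrially encoded list also failed without regular replicate 1 (adjusted p = 0.102) and without ketogenic replicate 1 (0.0694). With a gene length trend removed from log2 CPM its camera adjusted p was 0.272, against 0.0295 on log2 CPM with the trend kept.

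Cell cycle genes were shifted downward, with a median log2 fold change of -0.66 and a negative value for 32 of the 41 members. Their summed level was 765 ± 141 CPM on the regular and 538 ± 131 CPM on the ketogenic diet. The mitotic cyclin Ccnb2 had 24.9 ± 14.6 and 7.83 ± 5.72 CPM, the thymidylate synthase gene Tyms 16.6 ± 4.82 and 7.53 ± 3.31 CPM, the G1 cyclin Ccne1 14.7 ± 6.72 and 4.92 ± 3.83 CPM and the kinesin gene Kif23 6.58 ± 3.12 and 0.474 ± 0.821 CPM. Markers of erythroid cells moved the same way, with a median of -1.44 over 7 tested members, and the haemoglobin gene Hbb-bs had 28.1 ± 17.4 and 9.99 ± 3.02 CPM. The ratios of means of Ccnb2 (0.314) and Ccne1 (0.335) were 0.182 and 0.193 without ketogenic replicate 3, the library that held all ketogenic Kif23 counts, and that of Hbb-bs (0.356) was 0.55 without regular replicate 1. Camera gave adjusted p = 0.000498 for the cell cycle list and 0.00922 for the erythroid list. They had adjusted p = 0.708 and 0.634 with an estimated correlation. The erythroid list no longer passed without regular replicate 1 (adjusted p = 0.102), ketogenic replicate 2 (0.0903) or ketogenic replicate 3 (0.0715), nor without a low-count filter. By contrast, the cell cycle list passed with any 1 library left out.

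The remaining lists past camera's threshold were immunoglobulin constant regions, immediate early genes and the type I interferon response, all shifted upward. The 12 immunoglobulin constant genes had a median log2 fold change of 0.94, with 8 positive and 4 negative (adjusted p = 0.000103, and adjusted p = 0.314 with an estimated correlation). Their summed level, set mostly by Igkc and Ighm, stood lower on the ketogenic diet, at 489804, 452737 and 500974 CPM against 550229, 593594 and 551108 CPM. This list did not pass on ranks (adjusted p = 0.169). On log2 CPM, camera gave it an adjusted p of 0.0233 before and 0.21 after a gene length trend was removed. The interferon list had 0.0482 before and 0.0513 after, so most of its move from the main test came with the change to log2 CPM. In the immediate early list, 15 of 19 genes were positive with a median of 0.39, among them Fosb (21.7 ± 14.8 and 65.2 ± 31.1 CPM), Fos (285 ± 138 and 551 ± 85.7 CPM) and Btg2 (98.1 ± 6.05 and 150 ± 16.7 CPM). In the interferon list, 15 of 18 genes were positive with a median of 0.43, led by Ifi27l2a with 9.85 ± 4.63 and 50.4 ± 35.6 CPM and Bst2 with 35.5 ± 9.64 and 71.4 ± 29.1 CPM. The Ifi27l2a ratio of means of 5.12 was 3.07 without ketogenic replicate 2, and that of Fosb of 3.01 was 4.90 without regular replicate 2. Camera gave adjusted p = 0.00922 and 0.0157 for these lists, and adjusted p = 0.708 and 0.581 with an estimated correlation. The immediate early list did not pass without regular replicate 1 (adjusted p = 0.107) or ketogenic replicate 1 (0.19). The interferon list did not pass without regular replicate 1 (0.108) or regular replicate 3 (0.218). In total 8 of 33 lists passed with the preset correlation, 7 on ranks, and 0 with an estimated correlation or by fry's directional p, and fry's mixed p passed for the immunoglobulin constant regions.

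The metabolic lists that a ketogenic diet directly concerns did not pass. Ketone body metabolism and transport had a median log2 fold change of -0.32 over 8 genes, while camera's direction was upward (adjusted p = 0.799), and the transporter gene Slc16a6 had 7.49 ± 2.65 and 15.7 ± 3.29 CPM. Fatty acid oxidation and PPAR targets had a median of 0.07 over 28 genes (adjusted p = 0.309), with the dehydrogenase gene Acadl at 25.6 ± 6.11 and 43.3 ± 10.8 CPM. Glycolysis had a median of -0.32 over 20 genes (0.309), with the phosphofructokinase gene Pfkl at 27.6 ± 2.57 and 11.1 ± 3.42 CPM. The tricarboxylic acid cycle had a median of -0.36 over 23 genes (0.309), with Idh3a at 20.5 ± 10.6 and 8.38 ± 2.83 CPM. Cholesterol synthesis (-0.43 over 19 genes, adjusted p = 0.187), amino acid response (-0.32 over 25 genes, 0.206) and fatty acid synthesis (0.02 over 12 genes, 0.957) did not pass camera either.

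Lists of the secretory pathway and of plasma cell identity did not pass camera. ER chaperones and the unfolded protein response had a median of -0.05 over 32 genes (adjusted p = 0.799), and protein translocation and ER-Golgi transport -0.10 over 44 genes (0.514), with the oligosaccharyltransferase gene Stt3b at 84.7 ± 11.8 and 50.01 ± 12.7 CPM. Plasma cell identity had a median of 0.18 over 25 genes (0.187), with the ER prolyl isomerase gene Fkbp11 at 82.9 ± 6.28 and 163 ± 64.1 CPM. MHC class II and antigen presentation had -0.47 over 18 genes (0.0743), with H2-Ob at 26.8 ± 4.18 and 14.9 ± 3.08 CPM. N-glycan processing had a median of -0.21 over 19 genes (0.165), with camera downward and a mean of 0.07. Its member Mgat3, which adds bisecting N-acetylglucosamine, had 0 counts over the regular and 152 over the ketogenic libraries. That was 44.8-fold higher against a floor of 3 counts over the group and 25.7-fold without regular replicate 1. The exact counting interval for regular over ketogenic ran from 0 to 0.0278, and to 0.0484 without regular replicate 1. It treats reads as independent and leaves out the spread between libraries. In all, 10 genes had no count on the regular diet and at least 1 in each ketogenic library, and 5 had the reverse. In other splits of the libraries into 3 and 3, between 0 and 101 genes per side had this pattern. The niche receptor and adhesion list had a median of -0.37 over 29 genes (0.309), of which Ccr10 alone passed over the list alone.

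Of the other process lists, the medians were 0.31 for NF-kB targets (adjusted p = 0.309), 0.26 for the proteasome (0.57), 0.21 for antioxidant genes (0.803), 0.04 for apoptosis regulators (0.836) and 0.02 for heat shock genes (0.748). They were -0.10 for mTORC1 and AMPK signalling (0.397), -0.20 for autophagy and lysosome (0.892) and -0.34 for histone deacetylases and sirtuins (0.309). The mean of the antioxidant list was -0.14, opposite to its median and to camera's direction, and the apoptosis and fatty acid synthesis lists had means of -0.02 with medians and camera directions above 0. For markers of other cell types, medians were 0.24 for neutrophils (0.309), 0.03 for B cells (0.463), -0.45 for dendritic cells (0.784) and -0.80 for monocytes and macrophages (0.123). Summed neutrophil markers reached 1061 CPM in ketogenic replicate 2, against 358 to 482 CPM in the other 5 libraries. The markers of T and NK cells, megakaryocytes, stromal cells and the group of eosinophils, basophils and mast cells had fewer than 5 tested genes each. Prg2, an eosinophil granule protein gene, had 353 ± 62.4 and 744 ± 256 CPM.

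**Figure D3:**
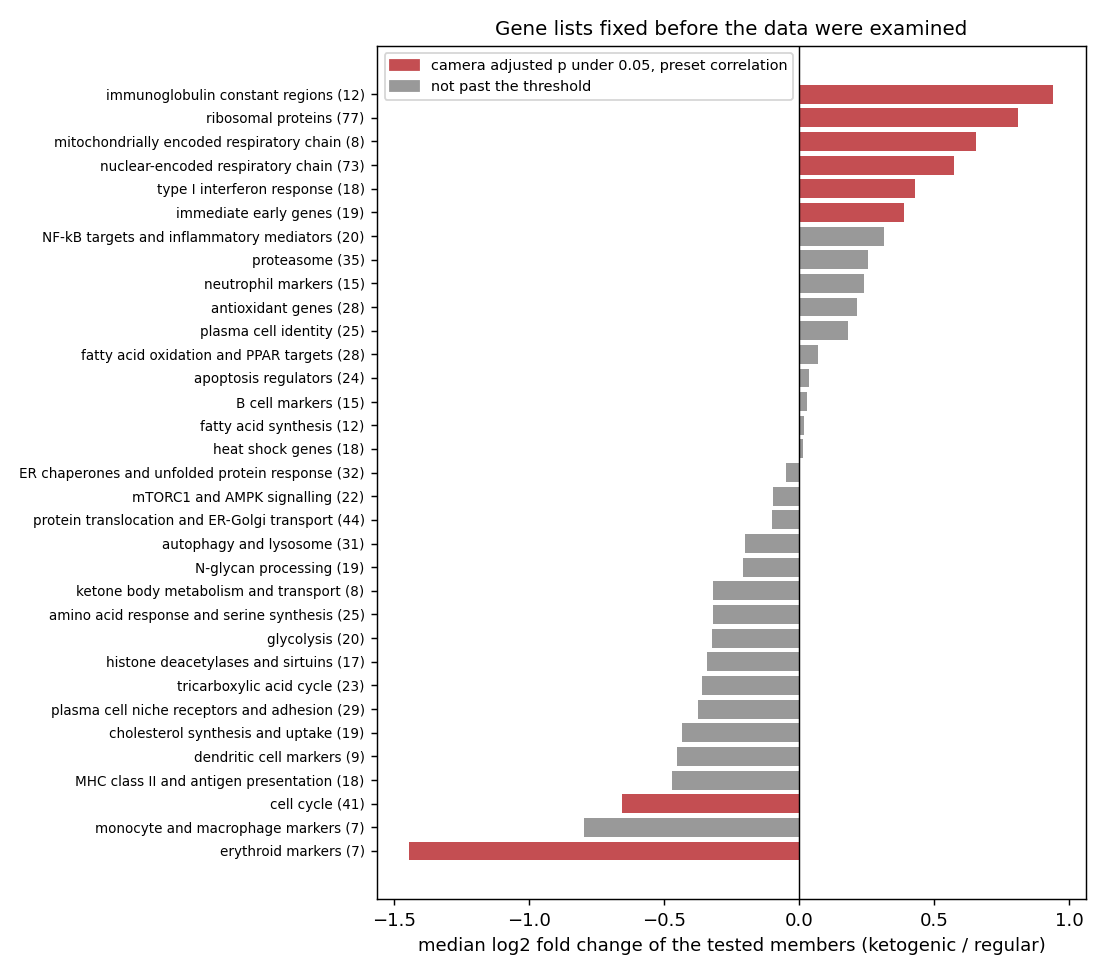
Median log2 fold change, ketogenic over regular, of the tested members of 33 gene lists (x axis), with the number of members in brackets; red bars passed camera with the preset correlation, grey bars did not. Ribosomal proteins stood at 0.81 and cell cycle genes at -0.66, and none of the red bars passed with an estimated correlation.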

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

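The fit without regular replicate 1 and ketogenic replicate 2, and the removal of a gene length trend, were chosen after seeing the data; the other alternatives were not. The count of genes, 0 by edgeR, was 15 without a low-count filter, 54 by DESeq2 and 3 by limma-voom, and 0 under the other scalings, filters, thresholds and every left-out library. The 3 genes passing over their list alone became 36 without the filter, 7 with the 5 CPM filter, 12 by DESeq2, 7 by limma-voom and between 1 and 73 with 1 library left out. The 8 lists became 0 with an estimated correlation, 0 by fry and 5 without both libraries (mitochondrially encoded, interferon and erythroid lost). With 1 library left out the number lay between 4 and 8, and was 4 without regular replicate 1. The length trend was removed from log2 CPM, which also changed the form of the test, and 5 lists passed. By camera on log2 CPM, adjusted p went from 0.0295 to 0.272 for mitochondrially encoded genes when the trend was removed. It went from 0.0233 to 0.21 for immunoglobulin constant regions, and only from 0.0482 to 0.0513 for the interferon response. The cause was not tested. Sort gate genes and other cell type markers stayed at 0 called in all fits. Same-numbered libraries did not pair (correlations of their deviations -0.05, -0.05 and 0.08, and not every library correlated best with its own number); with the replicate block, the counts were 0 genes, 3 list genes and 8 lists.

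Of the 154 named genes, 12 passed without the filter, by DESeq2 or by limma-voom, none with 1 library left out, and 8 changed sign, all with an SE larger than their log2 fold change. Kit (0.20) was -1.88 by limma-voom and -1.78 with the block, and Hdc (0.61) -1.58 with the block. Without both libraries Insig1 (-0.43) was 0.34, Acsl4 (-0.53) 1.40, Itga2b (-0.17) 0.64 and Prg3 (0.66) -0.22, and Trac (-0.21), which kept its sign, was -2.90. With 1 library left out, log2 fold changes spanned -4.14 to 1.35 for Kit, -2.76 to 1.38 for Hdc, -0.77 to 0.17 for Insig1, -0.97 to 1.05 for Acsl4, -0.85 to 0.41 for Itga2b, -2.68 to 0.37 for Trac and -0.18 to 0.29 for Apoe (0.12). The cause was not tested. DESeq2 and the fit with robust estimation switched off gave no list test, and genes under a stricter filter or taken out have no value there. In the simulation 7% of genes changed 4-fold were recovered, and 12.5% of the 8 with a log2 CPM of at least 5, too few to separate depth from spread. At 16-fold, 35% of all and 100% of the 16 with that log2 CPM were recovered. These shares need not hold for the real genes. The real Ighg1, 21.1-fold higher at a log2 CPM of 12.7, did not pass edgeR's test (adjusted p = 0.993).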

Other observations

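The tests of ketogenic replicate 2, of B cells, of exchanged reads and of other splits for the gene count, the haemoglobin share without regular replicate 1 and the fit without both low-correlation libraries, and the summaries of variable segments, were chosen after the results were seen. The effective number of kappa variable segments was higher in all 3 ketogenic libraries than in any regular one, while the number of segments with counts and the share of the leading segment overlapped. The effective number (the exponential of the Shannon entropy of their shares) was 23.5 ± 5.46 on the regular and 36.3 ± 8.16 on the ketogenic diet (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), and of heavy-chain segments 29.9 ± 7.67 and 43.2 ± 6.77 (exact permutation p = 0.2), with overlapping libraries. For the 3 lambda segments it was 2.02, 2.09 and 1.83 on the regular and 2.01, 1.65 and 1.29 on the ketogenic diet. Ighv1-26 was the most used heavy-chain segment in all 3 ketogenic libraries, with 19.0%, 5.69% and 11.02% of heavy-chain segment counts. The regular libraries had a different leading segment each: Ighv1-12 (9.61%), Ighv1-80 (18.3%) and Ighv1-9 (25.8%). Among genes with a log2 CPM of at least 5, the median SD within a diet was 1.11 on the log2 scale for immunoglobulin segments and 0.41 for other genes.

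The higher IgG and IgA and lower IgM share on the ketogenic diet was weighed first. Scaling by a few abundant genes cannot move a ratio within a library, and the log2 ratio of IgG and IgA to Ighm counts differed by 3.23 between diets, against 1.36 for the sum of the group SDs. B cells carrying Ighm into the regular libraries would lower B cell markers with Ighm, yet the median of the 15 tested markers lay 1.39 above the log2 fold change of Ighm, against a median absolute deviation of 0.44. Of these markers 9 were positive and 6 negative, and 2 lay lower without overlap, among them Fcmr (log2 fold change -1.15), against 0 higher. The MHC class II and antigen presentation list was lower too (median -0.47, camera adjusted p = 0.0743). B cells as part of the source are therefore not excluded. Reads exchanged between the IgG genes would leave their sum alone, and it differed by 30017 CPM, against 10314 for the sum of the SDs. A larger fraction of class-switched plasma cells on the ketogenic diet may be a hypothesis, which counts of IgM, IgA and IgG plasma cells, not analysed here, would test, and a few expanded clones or differences between the sorts stay open.

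The upward shift of ribosomal and respiratory chain genes was weighed next, since amplified libraries can favour short transcripts. These genes are short in the deposited length column (median 1770 and 1718 bases against 4192 for all tested genes). That column gives 1 length per gene, which need not be the length of the transcripts present. Both list medians, 0.81 and 0.57, lay at percentile 100 of 10000 random lists matched on that length and expression, where the matched medians were 0.16 and 0.23. The random lists were drawn gene by gene, without the correlation of the real lists, and transcript length itself was not matched. The comparison therefore does not decide whether length is the cause. Ketogenic replicate 2 did not carry the ribosomal shift alone, with a camera adjusted p of 3.49e-11 without it at the preset correlation (with all libraries, adjusted p = 0.708 with an estimated correlation) and 9814 CPM in ketogenic replicate 1 against at most 6210.0 CPM on the regular diet, although replicate 3 reached only 6395 CPM. The respiratory list had 0.189 without it and 0.000809 without it and regular replicate 1, so that how far its shift rests on that library stays open. RNA quality and the strong correlation within the ribosomal list (0.786) stay open too, beside an effect of the diet.

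The lower cell cycle list was weighed last. Its median length of 4217 bases in the deposited column lay near the 4192 of all tested genes, so a bias by that length would not be expected to shift it. Its median log2 fold change lay at percentile 0 of matched lists, which adds little to that. Erythroid precursors in the regular libraries could add cell cycle transcripts: the highest summed haemoglobin in a regular library, that of replicate 1, equalled 56.4% of the fall in summed cell cycle CPM, against 23.8% and 18.4% in the others. Without replicate 1 the highest was 29.6% of the fall then left, also between the bounds set beforehand. The assumption was that haemoglobin transcripts outweigh cell cycle transcripts in erythroid precursors. Haemoglobin lay below the fall of 227 CPM in every regular library. Its highest value was yet above the bound set beforehand for arguing against these cells, so the comparison does not decide. How far they or fewer dividing plasmablasts account for the fall cannot be told. The summed cell cycle level also overlapped between diets (602 CPM in regular replicate 2, 682 CPM in ketogenic replicate 3). Of 20 erythroid markers 7 were tested, and the sort on CD138 and CD267 would be expected to remove most erythroid cells. Summed haemoglobin was 74.5 ± 46.7 CPM on the regular and 27.5 ± 8.24 CPM on the ketogenic diet.

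The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8 lists, 1 of 10 splits did so, and the highest other gave 5. The edgeR gene count could not be tested in this way, since a real count of 0 is reached by all 10 splits by construction, and the highest other was 0. DESeq2 called 54 genes in the real split and 280 when regular replicate 1, ketogenic replicate 1 and ketogenic replicate 2 faced the rest. Another split (regular replicates 1 and 3 with ketogenic replicate 2) gave 64, and the other 7 gave 24 to 45. The split with 280 genes, singled out after the counts were seen, groups the 3 libraries with the fewest detected genes, and points to a structure of the samples beside the diet that was not tested further. At an unadjusted p under 0.05 edgeR had 558 genes there, 350 in the real split and between 104 and 322 in the remaining splits. In the split with 280 DESeq2 genes, 101 genes had no count in those 3 libraries and at least 1 in each of the others.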
